A study of Mus musculus with 9 samples.

How the data were processed

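Total RNA of isolated glomeruli from 9 samples in 3 groups of 3 was labelled with Cy3 and hybridised to one-colour Agilent mouse arrays, per the labels' protocols. The authors scanned the arrays and extracted them with Agilent Feature Extraction 11.5.1.1, per the file headers. Each deposited scanner file holds the spot intensity on a linear scale, as a processed signal that was background-subtracted, detrended and not normalized between arrays, per the file headers, next to the mean signal and the median background intensity. The probe coordinates are those of build mm9, per the file headers. The submitters' processing notes also name limma, without its role. The deposited value table of the series gives log2 values of the authors. Set against the scanner files, each of its columns closely matched the log2 processed signal of its own array minus a constant, with no centring of genes. The constant was close to the array's 75th percentile. For enarodustat replicate 1 the median difference was -7.9935, where minus the 75th percentile is -8.0004. The scale, centring and direction of the value table were thus found from the values, as none is stated, and none stays unknown. The medians of its columns were -3.07, -3.03 and -2.93 for wild-type vehicle, -3.10, -3.06 and -3.06 for ob/ob vehicle and -3.04, -2.95 and -3.05 for ob/ob enarodustat, replicates 1 to 3. All of its columns belong to a sample.

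Each array has 62976 spots, of which 3671 are controls and were left out, leaving 56605 probes in all. Spots marked as outliers were left out and the other spots of a probe averaged. A set of 32 probes with only outlier spots on an array was removed. The main values were log2 of the processed signal minus each array's 75th percentile over probes. A probe was kept when it was well above background on every array of at least 1 group (36671 probes), and a gene was represented by its probe with the highest mean over the 9 arrays. Probes of a gene that disagreed in sign are named where the gene is, and probes that differed only in size are named for some genes. The names come from the reference table of assembly GRCm38.p6, which was used for names only. Of the probes, 32994 were matched by accession, 10224 by symbol and 520 by synonym. Of the 12867 that were not matched, 2574 kept the name in the files and 10293 had none. The tests ran on 24150 features, 18479 with a gene name and 5671 without.

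The tests used limma 3.58.1 in R 4.3.3, with the data.table package in version 1.17.8, and the figures matplotlib 3.10.9 in Python 3.11.15. A linear model with 3 groups was fitted to all 9 arrays with lmFit, contrasts.fit and eBayes, so that the groups share an estimate of the spread, and p values were adjusted by the Benjamini-Hochberg method over the features of each comparison. Features were called at an adjusted p under 0.05. Gene lists of cell types, HIF targets, inflammation, matrix and metabolism, 26 of them with at least 5 tested members, were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists. Only with the preset correlation was any list called by camera. Groups, designs, lists, alternatives and the rule for naming genes were fixed before the data were examined. That rule takes the 10 largest called changes in each direction with groups that do not overlap, or the 5 smallest p values where fewer than 5 genes were called. It adds 20 anchor genes and, for each called list, up to 4 members with the smallest p, and skips predicted and clone names. Where a count of 5 or fewer is given, its genes are named too, and those outside this rule were chosen after their values were seen.

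Probes not well above background on any array of a group give a bound on the fold, as stated with the first such value. The fit was tested on simulated data for the 24150 features, with 200 changed genes in each of 10 simulations. Values were drawn independently for each feature with the moderated spread of limma, so variation shared between genes was not simulated. In the comparison of ob/ob vehicle with wild type, changes of 1.5-fold, 2-fold and 4-fold were recovered in 6.57%, 56.1% and 91.4% of cases. In the comparison of enarodustat with ob/ob vehicle they were recovered in 7.46%, 54.8% and 92.7%, and in that of enarodustat with wild type in 5.82%, 51.9% and 91.5%. The share of false calls was 3.76%, 5.42% and 6.95% in the 3 comparisons. For the 2 comparisons that share the ob/ob vehicle arrays, 100 simulations drew groups without effects, and again with the fitted ob/ob effect kept and no drug effect. For the share of opposite signs among called features, 100 more simulations drew all 9 arrays with the fitted ob/ob effect and no drug effect and called features anew, a calculation added after seeing the data.

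The alternatives were quantile normalization, normexp with an offset of 50 on mean and background intensity followed by quantile normalization, the array median, the authors' deposited log2 values, other filters and probe rules, other variance models and thresholds, array weights, fits of only the groups compared, blocks for replicate number and slide, and leaving out each array. Added after seeing the data were fits without the 2 arrays with the highest proximal tubule markers, a proximal tubule covariate, and ob/ob vehicle arrays that are not shared. Slide was tested as a batch only by leaving out enarodustat replicate 3, because 8 arrays lay on slide 1 and it alone on slide 2.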

Results

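Gene expression was measured in glomeruli, the filtering units of the kidney, isolated with magnetic beads from male mice of the BTBR strain at 22 weeks of age. Wild-type mice on control food were compared with ob/ob mice, which lack functional leptin and become obese and diabetic on this background. Another group of ob/ob mice received enarodustat in the food for 18 weeks. Enarodustat inhibits the prolyl hydroxylases that mark hypoxia-inducible factor (HIF) for degradation. Each group held 3 samples, each on its own one-colour array, 9 arrays in all. The labels do not say whether the 3 samples of a group came from single or pooled mice, so the tests measure the spread between these samples. The 75th percentile of the processed signal ranged from 210.4 to 325.3 units between arrays, and 62.3% to 68.3% of the probes were well above background. No spot was saturated. Correlations across probes were 0.973 to 0.991 between arrays of a group and 0.953 to 0.987 between arrays of different groups. All 4 Y-linked genes examined were well above background on all 9 arrays. In total 24150 genes and unnamed features were tested. Values are log2 signals relative to the 75th percentile of their array, means of groups are given ± SD (n = 3), and log2 changes ± SE of the limma fit. The number of arrays limits the precision of every value.

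The first comparison asks how glomeruli of ob/ob mice differ from those of wild-type mice, both on vehicle. Ccl2, a chemokine that recruits monocytes, was 24.4-fold higher in ob/ob glomeruli (1.61 ± 0.30 against -3.005 ± 0.40, log2 change 4.61 ± 0.24, limma adjusted p = 0.000173). Gpr176, an orphan G protein-coupled receptor, was 52.1-fold higher (0.82 ± 0.22 against -4.88 ± 0.28, log2 change 5.70 ± 0.18, adjusted p = 7.41e-06). Lgals3, the macrophage-associated lectin galectin-3, was 8.56-fold higher (log2 change 3.10 ± 0.19), and Fn1, which encodes the matrix protein fibronectin, was 5.73-fold higher (2.52 ± 0.31). Among podocyte genes, the transcription factor gene Lmx1b fell by 1.17 ± 0.14 on the log2 scale (adjusted p = 0.00335). In total 1823 features passed an adjusted p of 0.05 in limma, 1181 higher and 642 lower in ob/ob glomeruli, and 970 of these differed at least 2-fold. The values of the groups did not overlap for 7423 features, 30.7% of those tested, where chance gives 10%. The number called was 967 without wild-type replicate 2, 1176 without wild-type replicate 3, and 916, 1187 and 1117 without ob/ob vehicle replicates 1, 2 and 3. With the mean of the proximal tubule markers as a covariate, an alternative chosen after seeing the data, it was 632. It was 1005 without the filter on dim probes and 4181 with array weights.

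Among the named genes with the largest increases were also Qrfpr (32.8-fold), Gabra3 (29.3-fold), which encodes a subunit of the GABA-A receptor, and Spon2 (24.2-fold), a secreted matrix protein. Their adjusted p values in limma were 0.00497, 0.00132 and 0.00603. Qrfpr and Gabra3 were each well above background on 1 wild-type array, and Gpr176 on 2. The folds of these genes rest partly on signals near background, so their size and order are approximate. Spon2 had a wild-type value of -2.99 in replicate 2 against -0.85 and -0.61 in replicates 1 and 3, so its fold is approximate too. Where a probe was not well above background on any array of a group, the fold is a lower bound, set on each of those arrays against its dimmest signal that was well above background, or the gene's own value where that was higher. Mmp10, a matrix metalloproteinase, was thus at least 25.9-fold higher, Bean1 at least 8.90-fold, Mgarp at least 6.23-fold, Hpgds at least 4.37-fold and Tecrl at least 3.72-fold. The largest decreases among named genes were those of Lypd1 (at least 21.1-fold, adjusted p = 0.000223), the organic anion transporter gene Slc22a7 (at least 18.7-fold), Ranbp17 (at least 7.75-fold) and the glutamate receptor gene Grm7 (at least 5.45-fold). Creg2 was 11.8-fold lower, the calcium channel subunit gene Cacna2d2 10.5-fold, the serotonin receptor gene Htr7 8.65-fold, Adamdec1 8.15-fold, Brinp2 7.97-fold and the adrenergic receptor gene Adra2c 7.26-fold. These folds are approximate in the same way for Brinp2, well above background on 1 ob/ob vehicle array, and for Creg2, Htr7, Adamdec1 and Adra2c, on 2 each. Another probe of Ranbp17 was well above background on 2 ob/ob arrays, and with no filter on dim probes the gene is read from a different probe, with a log2 change of 0.42. The call of Slc22a7 (adjusted p = 0.0419) was lost when any array other than wild-type replicate 1 was left out, with an adjusted p of up to 0.131. Its wild-type values were -3.77, -0.48 and 1.82 in replicates 1 to 3, so its bound holds for their mean and not for each array. The call of Tecrl was lost without wild-type replicate 2 or ob/ob vehicle replicate 1 or 2 (up to 0.0671). That of Brinp2 was lost without wild-type replicate 1 or 2 or ob/ob vehicle replicate 2 or 3 (up to 0.0699). The probes lie on chromosome 11 from 81850650 to 81850709 for Ccl2, on chromosome 2 from 118103040 to 118103100 for Gpr176, on chromosome 9 from 7510011 to 7510070 for Mmp10 and on chromosome 1 from 127769280 to 127769340 for Lypd1, in build mm9 as in the files. Which exon or untranslated region each probe matches is not given in the sources used here.

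Of 28 tested monocyte and macrophage markers, 18 rose and none fell in ob/ob glomeruli over all genes tested, and 26 rose when adjusted over the list alone. The median log2 change of the list was 1.81. Besides Lgals3, the examples are Ctss, a lysosomal protease (2.55 ± 0.27), Fcer1g, an Fc receptor chain (1.82 ± 0.22), and Laptm5 (1.44 ± 0.15). The macrophage surface marker gene Adgre1 rose by 2.82 ± 0.49 (adjusted p = 0.0121) and Cd68 by 1.38 ± 0.26 (adjusted p = 0.0156). With camera and a preset correlation the list was called higher, with an adjusted p of 1.70e-17, and it had an adjusted p = 0.145 with an estimated correlation. Of 31 chemokine, cytokine and adhesion genes, 13 rose (18 higher and 1 lower, Cxcl12, when adjusted over the list alone), among them Ccl6 (2.44 ± 0.33), Ccl9 (2.04 ± 0.28) and the adhesion molecule gene Icam1 (1.49 ± 0.18). That list had an adjusted p = 0.0853 with an estimated correlation. Vcam1, another adhesion molecule gene, had a log2 change of 0.39 ± 0.43 (adjusted p = 0.637). Of 18 complement genes, 5 rose, namely C5ar1 (at least 2.96-fold), C3ar1 (at least 2.40-fold), C1ra (1.43 ± 0.18), Serping1 (1.38 ± 0.22) and C1s1 (1.24 ± 0.23). Adjusted over the list alone, 8 complement genes were higher and 1 lower, Cd55, and the list had an adjusted p = 0.292 with an estimated correlation. The call of C1s1 was lost without ob/ob vehicle replicate 1 or 3 (adjusted p up to 0.0558). The complement list was no longer called when only probes well above background on all 9 arrays were kept (adjusted p = 0.193).

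Of 48 genes of the extracellular matrix and TGF-beta, 20 rose and 2 fell (28 and 3 when adjusted over the list alone, where Postn is also lower). Col8a1 rose by 2.04 ± 0.17, the matrix metalloproteinase gene Mmp3 by 3.17 ± 0.32 and Col12a1 by 3.02 ± 0.37. The 2 genes that fell were Col1a2 (-1.13 ± 0.18) and Col15a1 (-1.86 ± 0.33). The call of Col15a1 was lost without wild-type replicate 2 (adjusted p = 0.0504). Col4a1, Col1a1, Tgfb1 and Ccn2 did not pass, with log2 changes of 0.87 ± 0.29, 2.10 ± 0.79, 0.68 ± 0.20 and 0.61 ± 0.28 and adjusted p values of 0.114, 0.152, 0.0749 and 0.236 in limma. Col1a1 passed without wild-type replicate 2 (log2 change 3.02) and Col4a1 without ob/ob vehicle replicate 1 (1.18). The matrix list was called higher by camera (adjusted p = 1.26e-10), with an adjusted p = 0.145 with an estimated correlation. Of 24 mesangial and vascular smooth muscle markers, 3 rose (4 when adjusted over the list alone, with Tbx18), namely Serpine2 (1.32 ± 0.15), the smooth muscle actin gene Acta2 (1.91 ± 0.31) and Cald1 (0.83 ± 0.15). Their probes differed in size. The 2 probes of Serpine2 ranged from 0.39 to 1.32, the 3 of Acta2 from 0.19 to 2.10 and the 5 of Cald1 from 0.14 to 1.16. With each probe tested as its own feature, 1, 2 and 3 of them were called. The mesangial list had an adjusted p = 0.398 with an estimated correlation, and the call of Cald1 was lost without ob/ob vehicle replicate 2 (adjusted p = 0.0514).

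Of 36 podocyte markers, 16 fell and none rose (24 when adjusted over the list alone), and the median log2 change was -0.73. The per-array medians of the list were 4.50 ± 0.10 in wild-type and 3.73 ± 0.10 in ob/ob glomeruli. Besides Lmx1b, the examples are Thsd7a (-1.48 ± 0.18), Pard3b (-1.28 ± 0.15) and Magi2 (-0.98 ± 0.13), which encodes a scaffold protein of the slit diaphragm. Nphs1, the nephrin gene, fell by 1.03 ± 0.22 (adjusted p = 0.0268), Wt1 by 0.87 ± 0.21 (adjusted p = 0.0427) and Vegfa by 0.72 ± 0.18 (adjusted p = 0.0469). The list was called lower by camera (adjusted p = 6.45e-15), with an adjusted p = 0.190 with an estimated correlation. The call of Nphs1 was lost without wild-type replicate 2 or 3 or ob/ob vehicle replicate 1 or 2 (adjusted p up to 0.0924). The calls of Wt1 and Vegfa were lost without any 1 of the wild-type or ob/ob vehicle arrays or enarodustat replicate 1 (up to 0.134 and 0.145). The Nphs1 probe maps to chromosome 7, 31266833 to 31267052 (mm9).

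Of 30 markers of glomerular endothelium, 7 rose and 1 fell (14 and 1 when adjusted over the list alone), with an adjusted p = 0.145 with an estimated correlation. Gpihbp1, which anchors lipoprotein lipase to capillaries, rose by 2.46 ± 0.23 and the fatty acid binding protein gene Fabp4 by 2.91 ± 0.43. The tight junction gene Cldn5 fell by 1.22 ± 0.23 (adjusted p = 0.0160). Its call was lost without wild-type replicate 2 or 3 or ob/ob vehicle replicate 1 (up to 0.0622). Of 36 interferon response genes, 6 rose (10 when adjusted over the list alone), including Oasl2 (1.12 ± 0.19) and Bst2 (1.06 ± 0.19), and the list had an adjusted p = 0.398 with an estimated correlation. Of 13 genes of NADPH oxidase and other sources of oxidants, 5 rose (5 when adjusted over the list alone), namely Rac2 (1.59 ± 0.15), Ncf1 (1.78 ± 0.21), Ncf4 (1.86 ± 0.27), Cybb (2.23 ± 0.39) and Xdh (1.43 ± 0.34). That list had an adjusted p = 0.145 with an estimated correlation. The call of Xdh was kept only without ob/ob vehicle replicate 2 or enarodustat replicate 2 and otherwise lost (adjusted p up to 0.123). Of 16 lymphocyte markers, 3 rose (7 when adjusted over the list alone), namely Lck (1.12 ± 0.15), Cd52 (1.45 ± 0.20) and Nkg7 (1.20 ± 0.27), and the list had an adjusted p = 0.145 with an estimated correlation. The call of Nkg7 was lost without wild-type replicate 2, any ob/ob vehicle replicate or enarodustat replicate 2 (up to 0.0991).

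HIF targets of glycolysis and glucose transport rose in 3 of 22 cases (8 when adjusted over the list alone), namely the lactate exporter gene Slc16a3 (0.81 ± 0.14), Pdk1 (0.92 ± 0.22) and the glucose transporter gene Slc2a3 (0.88 ± 0.22). The list had an adjusted p = 0.326 with an estimated correlation. The call of Pdk1 was lost without any wild-type replicate, ob/ob vehicle replicate 1 or 3 or enarodustat replicate 3 (adjusted p up to 0.130), and that of Slc2a3 without any array except ob/ob vehicle replicate 2 (up to 0.132). The 4 probes of Pdk1 ranged from -0.14 to 0.95 in log2 change. Of 40 other HIF targets, 6 rose and 2 fell (10 and 2 when adjusted over the list alone), with an adjusted p = 0.145 with an estimated correlation. Angptl4, an inhibitor of lipoprotein lipase, rose by 3.18 ± 0.40, Cp, the ceruloplasmin gene, by 2.25 ± 0.26, Loxl2 by 1.63 ± 0.23 and the endothelin gene Edn1 by 1.48 ± 0.24. The genes that fell were Vegfa and the transferrin receptor gene Tfrc (-2.20 ± 0.36). Egln3, Car9 and Slc2a1 did not pass, with log2 changes of -0.42 ± 0.31, 0.07 ± 0.13 and -0.28 ± 0.15. Egln3 passed without wild-type replicate 3 (-0.82), and the 2 probes of Car9 ranged from -0.28 to 0.07. The leptin receptor gene Lepr did not pass either (-0.22 ± 0.18), and its 3 probes ranged from -0.88 to 0.25.

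Markers of other cell types also differed between these arrays. Of 33 proximal tubule markers none passed, although all 33 were lower in ob/ob glomeruli with a median log2 change of -2.29, and the list was called lower by camera (adjusted p = 1.65e-07). It had an adjusted p = 0.535 with an estimated correlation. The per-array medians were 0.26, -0.33 and 3.42 in wild-type replicates 1 to 3 and -0.76, -0.11 and -2.49 in ob/ob vehicle replicates 1 to 3. Of 8 erythrocyte genes none passed, with a median of 1.59 and an adjusted p = 0.610 with an estimated correlation. The camera call of that list was lost without wild-type replicate 2 (adjusted p = 0.0958), wild-type replicate 3 (0.0971) or ob/ob vehicle replicate 3 (0.0814), and with the tubule covariate (0.522). Of 31 cell cycle genes none passed, and the camera call was lost without wild-type replicate 3 (0.490) or ob/ob vehicle replicate 2 (0.254), with the tubule covariate (0.819), without wild-type replicate 3 and enarodustat replicate 2 together (0.489) and with array weights (0.123). Of 25 NRF2 target genes 2 rose, Srxn1 (0.68 ± 0.14) and Gpx1 (0.62 ± 0.16), and the list call was lost without wild-type replicate 2 (0.0605), with quantile normalization (0.0839) and with normexp background correction (0.0733). The call of Srxn1 was lost without wild-type replicate 1 or 2 or any ob/ob vehicle replicate (adjusted p up to 0.0727), and that of Gpx1 without any array except wild-type replicate 3 (up to 0.141). The cell cycle and NRF2 lists had an adjusted p = 0.730 and an adjusted p = 0.145 with an estimated correlation. The lists of adipocyte, distal nephron, fatty acid oxidation, immediate early, lipogenesis, neutrophil, oxidative phosphorylation, parietal epithelium, renin-angiotensin and unfolded protein response genes were not called. Of these, the distal nephron list was called lower without wild-type replicate 1 (adjusted p = 0.00803) or ob/ob vehicle replicate 3 (0.0284). The fatty acid oxidation list was called higher without wild-type replicate 3 (0.00896), ob/ob vehicle replicate 2 (0.0482) or wild-type replicate 3 and enarodustat replicate 2 together (0.0105), and with the tubule covariate (0.00202). Called lower were the oxidative phosphorylation and unfolded protein response lists with quantile normalization (0.00135 and 0.0436) and normexp (0.000381 and 0.0348), and the lipogenesis list with the mean of probes (0.0463). Fry called the renin-angiotensin list higher (0.00675). Camera with a preset correlation called 16 lists, 14 higher and 2 lower, fry called 12, and none was called with an estimated correlation. Arbitrary splits of these 6 arrays called up to 14 lists with the preset correlation, while the highest count of features in such a split was 0. Each such split mixes the groups, so a group difference would widen its spread and also stay partly in its contrast. Its counts are therefore no exact reference for chance.

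**Figure D1:**
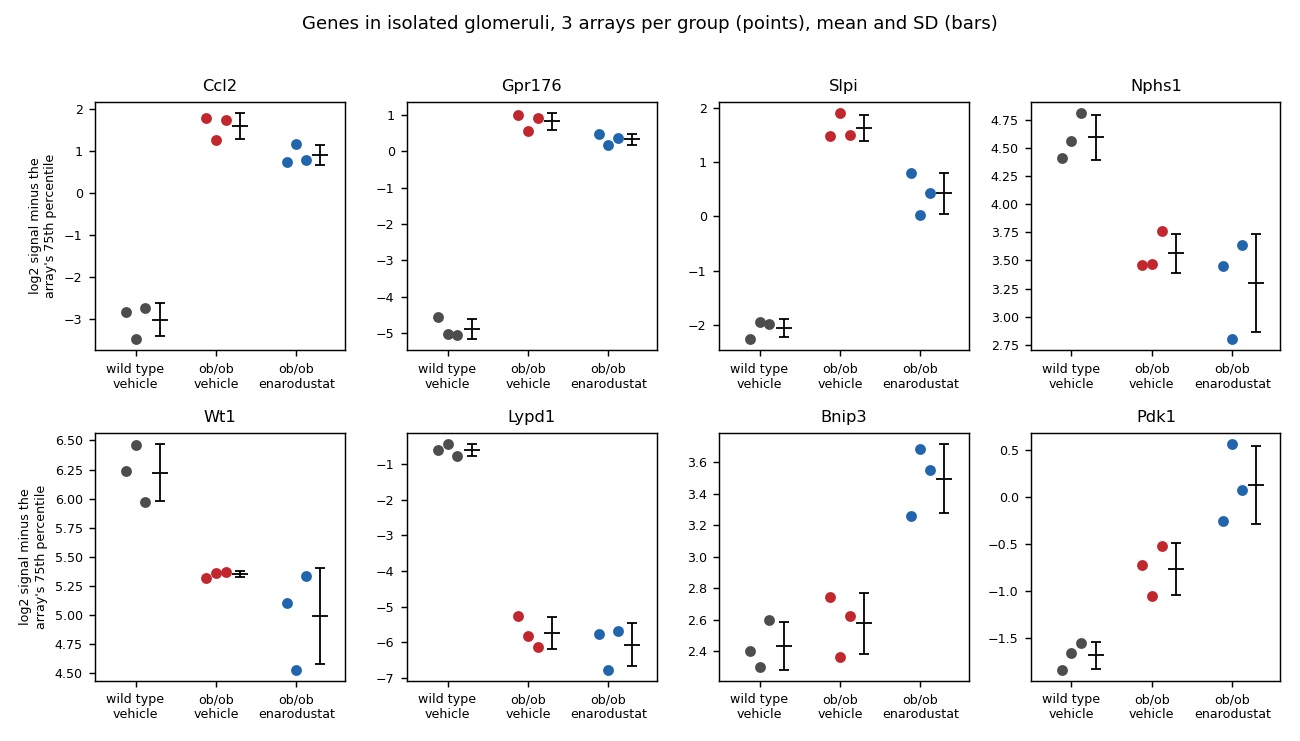
Log2 signal minus the 75th percentile of the array (y axis) of 8 genes in each of the 9 arrays, by group (x axis), where points are arrays and bars show the mean and SD of 3 arrays. Ccl2 and Gpr176 lie higher in both ob/ob groups than in wild type (Ccl2 1.61 and 0.91 against -3.005), Nphs1, Wt1 and Lypd1 lie lower, and Bnip3 lies at 3.50 with enarodustat against 2.58 in ob/ob vehicle.

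The second comparison asks what enarodustat changed in ob/ob glomeruli. No gene passed the threshold in limma. The smallest adjusted p was 0.204, and 1692 features had an unadjusted p under 0.05, where chance gives 1208. The named genes with the smallest p among those higher with enarodustat were the histone deacetylase gene Hdac11 (log2 change 1.76 ± 0.22, adjusted p = 0.204), the prostaglandin F receptor gene Ptgfr (1.21 ± 0.18), Spata33 (0.99 ± 0.17), Bnip3 (0.92 ± 0.16), a HIF target in mitophagy, and Lnx1 (2.29 ± 0.39). The last 4 had an adjusted p of 0.377. Among those lower were Col11a2 (-0.77 ± 0.12), Ccnj (-0.86 ± 0.15), the protease inhibitor gene Slpi (-1.21 ± 0.21), Man2c1os (-0.53 ± 0.10) and F13a1, a coagulation factor gene expressed by macrophages (-1.13 ± 0.22), with adjusted p values from 0.377 to 0.504. Each of these 10 genes had groups that did not overlap, as did 3862 features in all (16.0%, where chance gives 10%). Some of these genes had 2 probes that differed in size. They ranged from 0.40 to 1.21 for Ptgfr, -0.77 to -0.18 for Col11a2, -1.21 to -0.19 for Slpi and -1.13 to -0.47 for F13a1. Leaving out any array or changing any setting tried left the count of called features at 0. The smallest adjusted p in limma then ranged from 0.0575 without enarodustat replicate 3 to 0.643 without enarodustat replicate 2. It was 0.0799 without wild-type replicate 3. Simulated changes of 2-fold in this comparison were recovered in 54.8% of cases and changes of 4-fold in 92.7%. The simulations drew features independently with the moderated spread of limma, without variation shared between genes, so recovery in the data may be lower.

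Ccl2 was 0.91 ± 0.24 with enarodustat and 1.61 ± 0.30 with vehicle, a log2 change of -0.70 ± 0.24 that did not pass (adjusted p = 0.708), although the values of the groups did not overlap. Pdk1 had a log2 change of 0.89 ± 0.22 (adjusted p = 0.654), with 4 probes from -0.02 to 0.89, and Vegfa one of -0.44 ± 0.18 (0.708). Nphs1 and Wt1 had log2 changes of -0.27 ± 0.22 and -0.36 ± 0.21. Egln3, Slc2a1 and Car9 had changes of 0.42 ± 0.31, 0.21 ± 0.15 and -0.07 ± 0.13, and the 2 probes of Car9 ranged from -0.07 to 0.47. None of the other anchor genes was called, and Adgre1 had a change of -0.80.

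Of 22 HIF targets of glycolysis and glucose transport, none passed over all genes tested and 6 were higher when adjusted over the list alone. Their median log2 change was 0.27, and 19 of the 22 were higher with enarodustat. Examples are Slc16a3 (0.82 ± 0.14), the phosphofructokinase gene Pfkl (0.74 ± 0.14), the aldolase gene Aldoc (3.27 ± 0.72) and the glucose phosphate isomerase gene Gpi1 (0.44 ± 0.10), with adjusted p values in limma from 0.377 to 0.604. Aldoc also climbed within wild type, at -2.65, -1.26 and 0.20 in replicates 1 to 3. The distal nephron list medians of these arrays climbed alike, at -2.68, -0.78 and 1.20. Slc16a3, Pfkl and Gpi1 did not show this order in wild type. Whether the change of Aldoc came from distal nephron RNA was not tested. The HIF glycolysis list was called higher by camera (adjusted p = 1.01e-09), with an adjusted p = 0.480 with an estimated correlation and 0.0779 with fry. The per-array medians overlapped, at 1.95 ± 0.04 with vehicle and 2.03 ± 0.22 with enarodustat. Camera also called the erythrocyte list higher, with a median of 1.62 over 8 genes, none of them called. Its per-array medians overlapped (1.29 to 1.92 with vehicle and 1.46 to 3.64 with enarodustat). That list had an adjusted p = 0.577 with an estimated correlation, and its camera call was lost without enarodustat replicate 3 (adjusted p = 0.0813). Other HIF targets were not called as a list (camera adjusted p = 0.0787). That list was called higher without enarodustat replicate 2 (0.0456) or without wild-type replicate 3 as well (0.0320), with the tubule covariate (0.0156), quantile normalization (0.0443), the median in place of the 75th percentile (0.0344) and array weights (0.0471). Of its genes none passed over all genes tested, and 3 of 40 were higher when adjusted over the list alone, namely Bnip3, Bhlhe40 (1.12 ± 0.23) and Narf (0.56 ± 0.13). The last 2 were named after their values were seen.

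None of the 22 distal nephron markers passed (2 when adjusted over the list alone, Egf and Pvalb), although all 22 were higher with enarodustat, with a median of 2.11. The per-array medians of this list did not overlap, at -1.02 ± 1.45 with vehicle and 1.59 ± 0.79 with enarodustat. Examples are Egf (1.00 ± 0.22), Pvalb (3.15 ± 0.82) and Slc12a3, the thiazide-sensitive transporter gene (3.33 ± 1.01). The distal nephron list was called higher by camera (adjusted p = 5.54e-13), with an adjusted p = 0.480 with an estimated correlation and 0.445 with fry. Proximal tubule markers had a median of 1.47, with no call among 33, and their medians were -0.51, 2.11 and -0.64 in enarodustat replicates 1 to 3. Without enarodustat replicate 2 the camera call of that list was lost (adjusted p = 0.0565), and it had an adjusted p = 0.577 with an estimated correlation. Lists of fatty acid oxidation, oxidative phosphorylation and interferon response were called higher by camera, with medians of 0.17, 0.16 and 0.37 and no member called either way. Their adjusted p with an estimated correlation was 0.480, 0.577 and 0.577. Examples are Ppargc1a (1.75 ± 0.46), Cox4i1 (0.34 ± 0.13) and Irf1 (0.45 ± 0.17). Ppargc1a also climbed with the distal nephron medians within wild type (-0.84, -0.36 and 0.79 in replicates 1 to 3).

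Lists called lower by camera were podocyte, chemokine and macrophage genes, with medians of -0.22, -0.21 and -0.26 and no member called over all genes tested. The 3 lists had an adjusted p = 0.577, 0.480 and 0.662 with an estimated correlation. Adjusted over the list alone, 1 chemokine gene, Il18 (-0.86 ± 0.18), was lower. The call of the podocyte list was lost without enarodustat replicate 2 (adjusted p = 0.135) or without wild-type replicate 3 as well (0.129), and that of the macrophage list without ob/ob vehicle replicate 1 (0.880) or enarodustat replicate 3 (0.534). Examples are the lysozyme genes Lyz1 (-1.14 ± 0.32) and Lyz2 (-1.10 ± 0.32). Camera called 10 of 26 lists in this comparison, fry and camera with an estimated correlation called 0, and no list change is therefore described as a rise or fall. Arbitrary splits of the 6 arrays called up to 11 lists with the preset correlation.

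Some lists that camera did not call between the ob/ob groups were called when an array was left out or a setting changed. The cell cycle list was called higher without ob/ob vehicle replicate 2 (adjusted p = 0.000640) or enarodustat replicate 2 (6.15e-05), without wild-type replicate 3 as well (1.80e-06), with the tubule covariate (9.35e-05) and with array weights (0.0453). The complement list was called lower without ob/ob vehicle replicate 2 (0.000460) or enarodustat replicate 2 (0.0226), without wild-type replicate 3 as well (0.0244), with the tubule covariate (0.0486) and with no filter (0.0415). The matrix list was called lower without enarodustat replicate 3 (0.0278) and with no filter (0.0263). The lymphocyte list was called higher without ob/ob vehicle replicate 2 (0.0237), the unfolded protein response list lower without enarodustat replicate 1 (0.00238) and the lipogenesis list lower with the tubule covariate (0.0247).

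**Figure D2:**
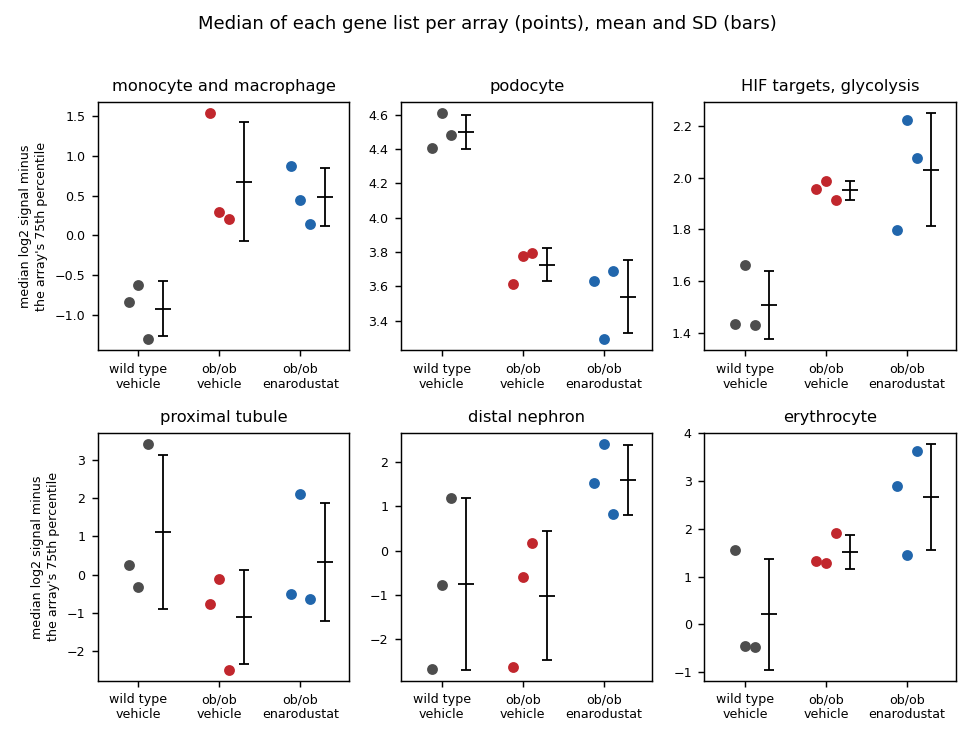
Median log2 signal minus the 75th percentile of the array (y axis) over the members of 6 gene lists in each of the 9 arrays, by group (x axis), where points are arrays and bars show the mean and SD of 3 arrays. Podocyte medians lie lower in both ob/ob groups than in wild type (3.73 and 3.54 against 4.50), and proximal tubule medians reach 3.42 in wild-type replicate 3 and 2.11 in enarodustat replicate 2.

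The next comparison sets ob/ob glomeruli with enarodustat against wild type, and asks what remained different under treatment. Ccl2 was 15.0-fold higher (log2 change 3.91 ± 0.24, limma adjusted p = 0.000499), Gpr176 37.1-fold higher and Lgals3 6.21-fold higher. Podocyte genes were lower, with Lmx1b at -1.29 ± 0.14, Nphs1 at -1.30 ± 0.22, Wt1 at -1.23 ± 0.21 and Vegfa at -1.16 ± 0.18. In total 2461 features passed, 1474 higher and 987 lower, and the values of the groups did not overlap for 7441 (30.8%, where chance gives 10%). Of these 2461, 1365 also passed between ob/ob vehicle and wild type, all in the same direction. They comprised 899 higher and 466 lower features, where 72 and 26 would be shared by independent lists of these sizes. Both comparisons use the same wild-type arrays, and the expected numbers do not allow for this. The number called was 1215 without wild-type replicate 2, and 1458, 1592 and 1365 without enarodustat replicates 1, 2 and 3. It was 1292 without wild-type replicate 3 and enarodustat replicate 2 together, a fit chosen after seeing the data, 1227 without the filter on dim probes and 4527 with array weights. Enarodustat replicate 3 lay alone on its slide, so a slide term equals leaving it out.

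The largest increases among named genes were those of Gpr176, Gabra3 (36.7-fold), Qrfpr (33.4-fold), Hif3a (28.8-fold), which encodes a HIF alpha subunit, Tent5b (22.6-fold), Clca3a2 (19.99-fold) and Vwa3a (17.6-fold). Ripor3 was at least 18.0-fold higher, with another probe well above background on 1 wild-type array, Bean1 at least 7.16-fold and Mgarp at least 6.89-fold. The call of Hif3a (adjusted p = 0.0197) was lost without any wild-type replicate or enarodustat replicate 1 or 3 (up to 0.0674). The largest decreases were those of Lypd1 (at least 18.3-fold), Slc22a7 (at least 16.0-fold), Htr7 (at least 7.33-fold), Ranbp17 (at least 6.61-fold, with another probe well above background on 1 enarodustat array), Mfsd2a (at least 6.29-fold), a transporter of lysophosphatidylcholine, and Grm7 (at least 4.65-fold). Brinp2 was at least 3.14-fold lower, Cacna2d2 9.28-fold, Gja3 8.27-fold and Arsi 6.52-fold. Folds are approximate for Gabra3 and Qrfpr, well above background on 1 wild-type array, for Gpr176, Hif3a and Clca3a2, on 2, and for Gja3 and Arsi, on 1 enarodustat array. Without wild-type replicate 2 the calls of Slc22a7, Mfsd2a, Gja3 and Brinp2 were lost. They were also lost without enarodustat replicate 3 for Slc22a7, Mfsd2a and Brinp2, without enarodustat replicate 1 for Mfsd2a and Gja3, without wild-type replicate 3 for Mfsd2a, and without wild-type replicate 1 or enarodustat replicate 2 for Brinp2. The highest adjusted p of these 4 genes was 0.0551, 0.0790, 0.0604 and 0.0714. With no filter Ranbp17 is read from a different probe, with a log2 change of 0.38. The bound of Slc22a7 again holds only for the mean of wild-type values that ranged from -3.77 to 1.82.

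Of 36 podocyte markers, 24 fell (28 when adjusted over the list alone), and the median log2 change was -0.96, with an adjusted p = 0.128 with an estimated correlation. Of 28 macrophage markers 17 rose (24 when adjusted over the list alone), with a median of 1.52 and an adjusted p = 0.127 with an estimated correlation. HIF targets of glycolysis and glucose transport rose in 13 of 22 cases (16 when adjusted over the list alone), with a median of 0.69 and an adjusted p = 0.106 with an estimated correlation. Slc16a3 rose by 1.63 ± 0.14, Pdk1 by 1.80 ± 0.22, Pfkl by 1.08 ± 0.14 and Aldoa by 0.65 ± 0.10. The probes of Pdk1 ranged from -0.16 to 1.80. Of the other HIF targets, 11 of 40 rose and 1 fell (14 and 2 when adjusted over the list alone), including Bnip3 (1.06 ± 0.16), with an adjusted p = 0.106 with an estimated correlation. The gene that fell was Vegfa, and Tfrc was also lower when adjusted over the list alone. In the direct comparison of the ob/ob groups none of these HIF targets passed in limma. Interferon response genes rose in 16 of 36 cases (30 when adjusted over the list alone), including Bst2 (1.54 ± 0.19), Oasl2 (1.58 ± 0.19) and Ifit3 (1.67 ± 0.25), with an adjusted p = 0.195 with an estimated correlation.

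Erythrocyte genes rose in 6 of 8 cases (7 when adjusted over the list alone), with a median of 3.29 and an adjusted p = 0.364 with an estimated correlation. Hba-a1 rose by 3.31 ± 0.74 (adjusted p = 0.0272), a call lost without wild-type replicate 2 or 3 or enarodustat replicate 1 or 3 (up to 0.0885). None of 33 proximal tubule markers passed, although all 33 were lower, with a median of -0.69. Camera did not call the proximal tubule list (adjusted p just above the threshold of 0.05), and it had an adjusted p = 0.796 with an estimated correlation. The list was called lower in 10 of 24 settings, the reported one counted among the 24. These include the settings without wild-type replicate 1 (adjusted p = 0.00382) or 2 (0.000801), ob/ob vehicle replicate 2 (0.0406) or 3 (0.0321) or enarodustat replicate 2 (6.70e-05). Distal nephron markers had a median of 1.94, with 1 of 22 called, Pvalb (3.37 ± 0.82, adjusted p = 0.0371). Adjusted over the list alone 0 distal nephron genes passed, and the list had an adjusted p = 0.553 with an estimated correlation. The call of Pvalb was lost without wild-type replicate 1 or 2, ob/ob vehicle replicate 3 or any enarodustat replicate (up to 0.114). Matrix genes rose in 17 of 48 cases and fell in 2 (24 and 2 when adjusted over the list alone), with an adjusted p = 0.169 with an estimated correlation. Chemokine and adhesion genes rose in 9 of 31 (12 when adjusted over the list alone), with an adjusted p = 0.106 with an estimated correlation. Endothelial markers rose in 9 of 30 and fell in 1, Cldn5 (14 and 1 when adjusted over the list alone), with an adjusted p = 0.128 with an estimated correlation. The call of Cldn5 (-1.15 ± 0.23) was lost without wild-type replicate 2 or 3 (up to 0.0647). The 2 matrix genes that fell were Col1a2 (-1.06 ± 0.18) and Col15a1 (-1.40 ± 0.33), the latter no longer called without wild-type replicate 2 or 3 or enarodustat replicate 1 or 3 (up to 0.103). Complement genes rose in 5 of 18 cases, namely C5ar1 (at least 1.81-fold), C3ar1 (at least 1.93-fold), C1ra (1.17 ± 0.18), Serping1 (1.33 ± 0.22) and C1s1 (1.01 ± 0.23), and Cd55 fell by 1.31 ± 0.19 (9 and 2 when adjusted over the list alone, where Cd59a is also lower). That list had an adjusted p = 0.364 with an estimated correlation, and its camera call was lost without enarodustat replicate 2 (0.0812), with normexp background correction (0.0570) and with probes well above background on all 9 arrays (0.501). The call of C1s1 was lost without wild-type replicate 2 or enarodustat replicate 1 or 3 (up to 0.0924), and that of C3ar1 without wild-type replicate 1 or 2 or enarodustat replicate 1 or 2 (up to 0.0668).

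Lymphocyte markers rose in 7 of 16 cases (7 when adjusted over the list alone), including Lck (1.22 ± 0.15) and Cd52 (1.30 ± 0.20), with an adjusted p = 0.106 with an estimated correlation. Genes of fatty acid oxidation and PPAR targets rose in 9 of 38 (11 higher and 1 lower, Cpt2, when adjusted over the list alone), including the lipid droplet gene Plin2 (1.22 ± 0.14), with an adjusted p = 0.280 with an estimated correlation. Genes of NADPH oxidase and other sources of oxidants rose in 5 of 13 (6 when adjusted over the list alone), namely Rac2 (1.25 ± 0.15), Ncf1 (1.503 ± 0.21), Xdh (1.90 ± 0.34), Ncf4 (1.24 ± 0.27) and Cybb (1.57 ± 0.39), with an adjusted p = 0.106 with an estimated correlation. The call of Ncf4 was lost without any wild-type replicate or enarodustat replicate 1 or 2 (up to 0.0805), and that of Cybb without wild-type replicate 2 or 3, ob/ob vehicle replicate 1 or 2 or any enarodustat replicate (up to 0.110). Mesangial markers rose in 3 of 24 (3 when adjusted over the list alone), namely Serpine2 (1.16 ± 0.15), Acta2 (1.76 ± 0.31) and Cald1 (0.76 ± 0.15), with an adjusted p = 0.364 with an estimated correlation. The 2 probes of Serpine2 ranged from 0.098 to 1.16, the 3 of Acta2 from 0.0016 to 1.76 and the 5 of Cald1 from 0.31 to 0.83. The call of Cald1 was lost without enarodustat replicate 1 or 3 (up to 0.0564). NRF2 targets rose in 2 of 25 (4 when adjusted over the list alone, with Gclc and Srxn1), Nqo1 (1.24 ± 0.20) and Gpx1 (0.64 ± 0.16), with an adjusted p = 0.106 with an estimated correlation. The call of Gpx1 was lost without any array except wild-type replicate 3 (up to 0.113). Of 31 cell cycle genes 1 rose (1 when adjusted over the list alone), Mcm6 (0.64 ± 0.12), a call lost without enarodustat replicate 3 (0.0502). That list had an adjusted p = 0.584 with an estimated correlation, and its camera call was lost without wild-type replicate 3 (0.0681). None of 49 oxidative phosphorylation genes passed, with a median of 0.15 and an adjusted p = 0.641 with an estimated correlation. The camera call of that list was lost without enarodustat replicate 2 (0.0812), without wild-type replicate 3 as well (0.104), with quantile normalization (0.532) and with normexp (0.437). Among lists not called, the unfolded protein response list was called lower without wild-type replicate 2 (0.0278) or enarodustat replicate 1 (0.00170), with no filter (0.0324), quantile normalization (0.0251) and normexp (0.0156). The lipogenesis list was called lower without wild-type replicate 2 (0.0255) and with no filter (0.0329), and the immediate early list higher without wild-type replicate 1 (0.0264). Camera called 18 of 26 lists, fry 13, and none was called with an estimated correlation, while arbitrary splits called up to 14.

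The last comparison asks whether the differences between ob/ob and wild-type glomeruli moved back under the drug. No gene passed in both comparisons with opposite direction, as none passed in limma between the ob/ob groups. Of the 1823 features that differed from wild type, 65.2% had a log2 change of opposite sign with enarodustat (820 of the 1181 higher and 369 of the 642 lower). Both comparisons use the same ob/ob vehicle arrays. In simulations with the fitted ob/ob effect and no drug effect, with features called anew each time, the share was 63.0% (61.0% to 64.6% over 100 simulations). A simulation that followed the features called in the data, without simulating their choice, gave 50.2% and is no reference for a share among chosen features. The former was added after seeing the data and called 4237 features on average, more than the 1823 in the data, so it is only an approximate reference. The share of 65.2% is therefore not taken as an effect of the drug. With ob/ob vehicle arrays that were not shared, the share was 67.0%, 46.7% and 60.0% when replicate 1, 2 or 3 was kept for the drug comparison alone, a calculation chosen after seeing the data. The share therefore depended on the array used. Across the 24150 features, which are not independent replicates, the 2 log2 changes had a correlation of -0.30. Simulations that share the ob/ob vehicle arrays gave -0.50 (-0.53 to -0.47) without any effect, and -0.21 (-0.24 to -0.18) with the fitted ob/ob effect kept and no drug effect. The observed value lies between these references, and the latter holds the noise of the fitted effect as well. The covariance was -0.0657 against -0.0362 in simulations, which draw genes independently with the moderated spread of limma, so the values leave open whether the differences moved back. The correlation was -0.13 without wild-type replicate 3 and -0.19 without enarodustat replicate 2, the arrays with the highest proximal tubule medians.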

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

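The fits with a proximal tubule covariate, those without wild-type replicate 3 and enarodustat replicate 2, and those with ob/ob vehicle arrays not shared were chosen only after the results were seen. Between ob/ob vehicle and wild type, 1823 features were called, and 1005 with no filter, 4181 with array weights, 632 with the tubule covariate, 970 at a log2 change of at least 1, 3103 at an adjusted p under 0.1 and 916 to 1774 without 1 array. Between enarodustat and wild type the 2461 became 1227 with no filter, 4527 with array weights, 1292 without the 2 arrays, 1127 at a log2 change of at least 1, 4044 at an adjusted p under 0.1 and 1215 to 2163 without 1 array. Between the ob/ob groups 0 features were called in every setting run. Apart from the block for slide (1365 between enarodustat and wild type), the other settings gave counts within 1.5 times, such as 1754 and 2465 with quantile normalization. Thresholds act by construction, and otherwise the cause was not tested.

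With the replicate number as a block, as for paired samples, 1408, 0 and 1954 features and 16, 10 and 18 lists were called. With the slide as a block, which equals leaving out enarodustat replicate 3, 1365 features were called between enarodustat and wild type. Over the 3 comparisons, residual correlations of same-numbered arrays ranged from -0.31 to 0.27 and those of other pairs from -0.37 to 0.48. Between the ob/ob groups same-numbered arrays had 0.13, 0.27 and -0.04, and other pairs -0.23 to 0.15. With 3 same-numbered pairs per comparison this check cannot tell whether samples were paired, and the labels do not say. The replicate block kept 155 of 163 calls of named genes.

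With an estimated correlation 0, 0 and 0 lists were called in the 3 comparisons, and fry called 0 in that of the ob/ob groups. The correlation of the 2 log2 changes was -0.18 with array weights and -0.42 to -0.13 without 1 array. The odds ratio near Lep, 1.32 at 20 Mb (exact p = 0.152), was 1.35 at 50 Mb (interval 1.01 to 1.79, exact p = 0.0377), past the threshold of 0.05, and 1.04 at 10 Mb (exact p = 0.873). The share moving back was 46.7% and 60.0% with ob/ob vehicle replicate 2 or 3 used for the drug alone. The cause was not tested.

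Ranbp17 turned to 0.42 (ob/ob vehicle against wild type) and 0.38 (enarodustat against wild type) with no filter, where a different probe is read. Between the ob/ob groups Lepr turned to 0.0177 with quantile normalization and 0.0121 with normexp. With normexp, the log2 changes of Egln3, ob/ob enarodustat against wild-type vehicle, and of Car9, ob/ob enarodustat against wild-type vehicle, turned to -0.0126 and -0.00623. Without 1 array, log2 changes between ob/ob vehicle and wild type ranged for Car9 from -0.0337 to 0.17 and Vcam1 from -0.00632 to 0.82. Without 1 array, log2 changes between the ob/ob groups ranged for Car9 from -0.17 to 0.0376, Fn1 from -0.26 to 0.24, Tgfb1 from -0.16 to 0.15, Ccn2 from -0.34 to 0.0920, Cd68 from -0.39 to 0.00519, Icam1 from -0.23 to 0.0401, Vcam1 from -0.41 to 0.41 and Lepr from -0.10 to 0.11. Without 1 array, log2 changes between enarodustat and wild type ranged for Egln3 from -0.39 to 0.32, Car9 from -0.0462 to 0.0548 and Slc2a1 from -0.20 to 0.0242. None of these except Ranbp17 was called, and the cause was not tested. Of 163 calls of named genes, 153 were kept with normexp, 159 with quantile normalization, 135 with no filter and 163 with the authors' deposited values. Leaving out 1 array kept 1287 of 1467 and reversed none. Signal over background limits genes such as Mmp10 and Lypd1 to lower bounds of the fold.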

Other observations

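The scan of gene families, the tests of tubule carry-over, of podocyte share and of other HIF targets were chosen only after the results were seen. Families were taken from shared symbol stems, the letters before the first digit, 288 of them with at least 8 tested genes. Each was compared with the other genes whose symbols hold such a stem, predicted and clone names left out. The test was Fisher's exact test, one-sided, with p adjusted over the families within each comparison and direction. The protocadherin beta genes, cell adhesion genes clustered on chromosome 18, were called higher in ob/ob vehicle than in wild type in 10 of 16 cases (62.5% against 6.04% of the others, exact test adjusted p = 1.13e-06). Their probes lie between 37427011 and 37680728 (mm9), and the median log2 change was 0.67. Examples are Pcdhb17 (0.81 ± 0.13) and Pcdhb6 (0.78 ± 0.14). With enarodustat against ob/ob vehicle the median was -0.04 and none was called in limma. Probes of such similar genes can bind transcripts of each other, so the 10 calls are not independent.

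Matrix metalloproteinase genes were called higher in 7 of 14 cases (exact test adjusted p = 0.000524), including Mmp10 and Mmp3, and C-type lectin genes in 8 of 26 (0.00524), including Clec7a. Among the Serpina genes, 6 of 16 were called higher (0.00991), including Serpina1a (1.75 ± 0.26) and Serpina1b (1.53 ± 0.20), which are close paralogs. With enarodustat against wild type, the matrix metalloproteinase, C-type lectin and Serpina families did not pass (exact test adjusted p = 0.0801, 0.0794 and 0.113). The Cd and Rgs families also passed in ob/ob vehicle against wild type (18 of 78 and 6 of 20, exact test adjusted p = 7.67e-05 and 0.0340). These families were not fixed in advance, and the Ccl and Col families overlap the lists already described. The exact test treats genes as independent and allows for no correlation between them, so the p values of all families can be too small.

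The first pattern is the number of features that differ between ob/ob vehicle and wild type. Of 10 splits of the 6 arrays 1, the real one, gave as many (1823, highest other 0), and for enarodustat against wild type 1 of 10 (2461, highest other 0), but 10 splits are too few for a share under 0.05. The other splits also mix the groups, so a group difference would widen their spread and lower their counts of features. A strain segment carried with the ob mutation could add called genes near Lep, and within 20 Mb the odds ratio was 1.32 (29 of 299 against 1782 of 23688, confidence interval 0.865 to 1.95, exact p = 0.152). With 50 Mb the ratio passed (1.35, interval 1.01 to 1.79, exact p = 0.0377) and with 10 Mb it did not (1.04, exact p = 0.873), and the bound set in advance, an interval including 1, was too weak, since the 20 Mb interval also includes 1.95, so a contribution near Lep stays open, while 1782 called features lie outside the 20 Mb window. Between the ob/ob groups all 10 splits gave at least the real count of 0 (highest other 2), and lists were called as often in 1, 2 and 1 of 10 splits in the 3 comparisons (16, 10 and 18, highest others 14, 11 and 14), again too few splits.

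The second pattern is the lower podocyte list in ob/ob glomeruli, with a median of -0.73. If tubule carry-over were the whole cause, taking out the tubule signal would bring the median towards 0, but with the proximal tubule list as a covariate it was -0.90, against a spread of 0.101 between arrays, and tubule markers were lower in ob/ob glomeruli, with a median of -2.29, where dilution of podocyte RNA needs more tubule signal. A lower share of podocytes alone would raise the markers of other cell types alike. The median log2 change of the macrophage list was 1.49 above that of the endothelial list. The spread of 0.816 is that of the difference between per-array list medians, which is another measure. Per-array medians rose from -0.92 ± 0.34 to 0.68 ± 0.74 for macrophages and from 3.81 ± 0.24 to 4.67 ± 0.22 for endothelium. By these medians the rises differed by less than 0.816, so the test cannot decide and a lower share of podocytes stays open. More macrophages, together with fewer podocytes or lower expression in each podocyte, may account for the values and stay open. The ob/ob genotype is confounded with any such shift in cell types, and no test separated them.

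The last pattern is the higher HIF glycolysis list with enarodustat, which is not established, since its per-array medians overlapped and no estimated correlation kept the call. Its median of 0.27 was 0.23 without the 2 arrays with the highest proximal tubule medians. With the erythrocyte list as a covariate it was 0.31, against a spread of 0.218. Of the 2 arrays left out, only enarodustat replicate 2 is in this comparison. The distal nephron list had per-array medians that did not overlap between the ob/ob groups (-1.02 ± 1.45 with vehicle and 1.59 ± 0.79 with enarodustat). Carry-over from the distal nephron was not tested. The values of 0.23 and 0.31 lie above 0.5 times the median of 0.27 by less than the spread of 0.218. The median of 0.27 itself does so too, so the test could not have excluded carry-over from proximal tubules or erythrocytes. Whether either contributes stays open. If stabilised HIF raised its targets in general, the list of other HIF targets would be higher too, and its camera adjusted p was 0.0787 as reported and under 0.05 in 6 other settings (0.0320 without the 2 arrays), so this is undecided. A biological effect of the drug therefore stays open.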
